A study of Bos taurus with 30 samples.

How the data were processed

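RNA was measured in corpus luteum tissue of 30 Angus crossbred heifers, 5 in each of 6 groups given by 2 days of the estrous cycle (day 4 and day 11) and 3 times after PGF2α (0, 4 and 24 h, with saline at 0 h). Each heifer gave tissue for 1 array. The authors describe a factorial, completely random design. Total RNA was labelled with biotin as cRNA and hybridized to the Affymetrix GeneChip Bovine Genome Array.

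The deposited values are log2 signals per probe set, which the authors made from the scanned arrays with RMA, a method that subtracts background, normalizes between arrays and summarises the probes of a probe set. The authors state neither the version of RMA nor which arrays were normalized together. The values ran from 1.80 to 14.35, with array medians of 6.01 to 6.16, the range of log2 values rather than of raw signals. They were used as deposited.

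Of 24128 probe sets in the table, 112 control probe sets were left out and 24016 were tested. The platform annotation gave 13292 of these exactly 1 gene symbol, 86 several symbols and 10638 none. The named probe sets stood for 9155 genes. Where a gene had more than 1 probe set, as 2913 genes did, the probe set with the highest mean over the 30 arrays represented it. Identifiers in parentheses are Entrez Gene numbers from the annotation; genome positions were not used.

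All 30 arrays were fitted together in limma 3.58.1 under R 4.3.3, with a mean per group and no block or covariate, and the variances were moderated by empirical Bayes with default settings. The fit left 24 residual degrees of freedom, 28.2 after moderation. The contrasts were 24 h and 4 h against 0 h within each day, day 11 against day 4 at 0 h, 24 h against 4 h within each day, and the difference between the days of the 4 h and of the 24 h response (the interaction). A moderated F test covered both interactions. Within each contrast the p values were adjusted over all probe sets by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. The text also counts, over all probe sets tested and not among those called, the ones where the 5 values of each group did not overlap. Group values are mean ± SD, and differences are given with their standard error.

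A total of 35 gene lists with 1115 entries, of which 855 were measured, were written from general knowledge of luteal and immune biology. The lists, the contrasts, the test, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated. Each list was tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The test fry, which asks whether the genes of a list move 1 way on balance, was run in addition. List p values were adjusted over the 35 lists within a contrast, and the number of members called was also counted with p values adjusted over the list alone.

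The genes named were, per contrast, the 8 with the largest rise and the 8 with the largest fall among called genes with no overlap between the groups (no such condition for interactions), up to 4 called members of each list with the largest change (2 with the smallest p where none was called), and a fixed panel of luteal and early response genes. The text names those with a known function. The panel genes reported were STAR, CYP11A1, HSD3B1, LHCGR, PTGFR, PTGS2, VEGFA, FGF2, EDN1, CCL2, CXCL8, FOS, NR4A1, INHBA and OXT. Exceptions to this rule are HBB and the measures of single arrays in the closing section.

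Signs of RNA and array quality (the 3′ minus 5′ difference of actin and GAPDH control probe sets and the array median) were compared between groups by exact two-sided permutation tests, with Benjamini-Hochberg adjustment. The smallest adjusted p of the planned tests was 0.47. The smallest p that 5 arrays against 5 can give is 0.0079, which alone could not pass the adjustment, so these tests do not show that quality was alike.

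The test was tried on simulated data, with changes of known size added to random normal values around the mean of each probe set. The SD of each probe set was pooled over the real groups and was the same in all groups. Probe sets were drawn independently. The shares below therefore say nothing about unequal spread between groups or about genes that vary together. For the day 11, 4 h contrast, 52.0% of changes of 0.5 log2 units, 96.5% of changes of 1 and 99.5% of changes of 2 were recovered, with 6.20% false calls, and a contrast without changes gave 0 calls. For the 4 h interaction the shares were 21.5%, 85.0% and 97.5%, with 6.05% false calls.

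The alternatives were quantile normalization, subtraction of array medians, leaving out the dimmest 30% of probe sets, a variance trend with robust moderation, array weights, replicate numbers as a block, a fit to the arrays of a contrast alone, an adjusted p under 0.01, a minimum change of 2-fold, keeping control probe sets, the mean of all probe sets of a gene, and leaving out each array in turn. Their effect is given in the closing section. The plots were drawn with matplotlib 3.10.9.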

Results

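Gene expression was measured in the corpus luteum, the gland that forms in the ovary after ovulation and secretes progesterone. The tissue came from 30 Angus crossbred heifers on day 4 or day 11 of the estrous cycle, and RNA from each animal was hybridized to 1 Affymetrix GeneChip Bovine Genome Array. Prostaglandin F2α (PGF2α), the hormone that triggers regression of a mature corpus luteum, had been given 4 or 24 h before collection, and animals given saline served as the 0 h controls. This made 6 groups of 5 arrays, and the number of arrays limited the precision of every value. Array medians lay between 6.01 and 6.16 log2 units, and the median SD between arrays of a group was 0.198. Within groups, arrays correlated at 0.978 to 0.994 across probe sets, which are not independent replicates.

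Most groups of arrays lay apart by day of the cycle and time after PGF2α, but day 4, 24 h replicate 1 lay among the day 4, 0 h arrays. The first principal component held 36.5% of the variance and the second 16.3%. Values below are log2 signals, differences of group means carry the standard error (SE) of the limma fit, and group values are given as mean ± SD.

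**Figure D1:**
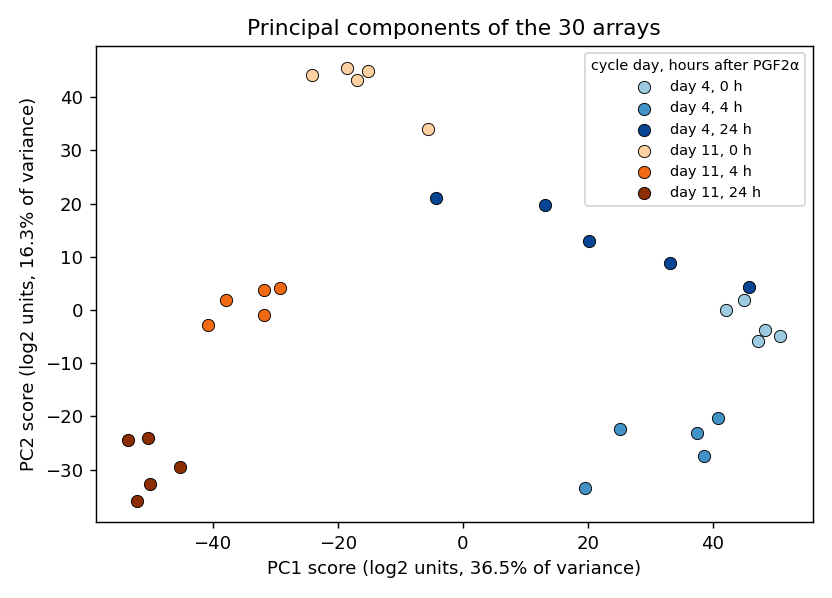
Scores of the 30 arrays on the first principal component (horizontal, 36.5% of the variance) and the second (vertical, 16.3%), in log2 units; each point is 1 array, colored by group with 5 arrays per group. Arrays of the same group lie near each other, apart from the day 4, 24 h group, whose 5 arrays are spread out.

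The day 11 and day 4 glands were first compared at 0 h, to describe the tissue that PGF2α reached. Genes of cell division were lower on day 11. Of 44 measured members of the cell cycle and mitosis list, 41 were lower (41 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation), with a median log2 difference of -2.15. Of 30 lysosome and autophagy genes 16 were higher and 4 lower (17 and 5 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation). PRLR (Entrez Gene 281422), the prolactin receptor, had a signal of 7.51 ± 0.20 (SD, n = 5) on day 11 and 4.09 ± 0.24 (SD, n = 5) on day 4.

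CCNB1, a cyclin that drives entry into mitosis, differed by -3.73 ± 0.45 (SE), and CCNA2, a cyclin of S phase and mitosis, by -3.07 ± 0.38 (SE). UBE2C, which marks mitotic proteins for destruction, differed by -3.06 and RRM2, a subunit of ribonucleotide reductase, by -3.02. KRT18, an epithelial keratin, was the gene with the largest difference, at -5.10 ± 0.29 (SE), or 34.3-fold lower. AREG, a ligand of the epidermal growth factor receptor, differed by -3.28 and LOXL4, a collagen cross-linking enzyme, by -3.73. PTGES, which makes prostaglandin E2, differed by -2.12 and PLAUR, the urokinase receptor, by -1.51.

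LHCGR (281900), the receptor for luteinizing hormone, was higher on day 11 by 1.22 ± 0.29 (SE). STAR (281507), which carries cholesterol into mitochondria for steroid synthesis, was higher by 0.73 ± 0.21 (SE). CYP11A1 (338048), which makes pregnenolone from cholesterol, was higher by 0.24 ± 0.07 (SE). OXT (280888), which encodes oxytocin, was lower, with a difference of -0.31 ± 0.07 (SE). The differences of HSD3B1 (281824), which makes progesterone, and of PTGFR (282020), the PGF2α receptor, did not pass the test (0.15, adjusted p = 0.61, and 0.01, adjusted p = 0.96). Of 27 cholesterol synthesis and uptake genes, 17 were higher and 1 was lower (19 and 1 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation). LPL, a lipase that frees fatty acids, was higher by 3.22, and CTSF, a lysosomal protease, by 3.32. INSL3, an insulin-like hormone of theca cells, was higher by 2.50 ± 0.54 (SE).

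The complement components C1QB, C1QC and C1QA, made by macrophages, were higher by 2.49, 2.42 and 2.14. The complement list had 13 of 21 genes higher (adjusted p = 0.39 with an estimated correlation), and the macrophage list had 11 of 20 higher and 1 lower (adjusted p = 0.58 with an estimated correlation). BOLA-DRA, a chain of the MHC class II molecule that presents antigen, was higher by 1.35. Among the endothelial markers 11 of 19 were higher, such as TIE1 by 1.09, and PLVAP and SELE were lower, with differences of -2.42 and -2.19 (adjusted p = 0.39 with an estimated correlation). Of the 31 hypoxia and glycolysis genes 16 were lower, such as the lactate transporter SLC16A3 at -1.99, and 3 higher, such as the aldolase ALDOC at 2.41 (16 and 3 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation). In total 8128 of 24016 probe sets differed, 3879 higher and 4249 lower on day 11. Over all probe sets tested, called or not, 5614 had no overlap between the 5 values of each day (0.794% by chance). Signs of RNA and labeling state examined in addition to the planned ones also differed between the days: the EF1A control probe sets had a 3′ minus 5′ difference of -2.17 on day 11 and -2.37 on day 4 (exact two-sided permutation p = 0.024, adjusted p = 0.36), and the labeling controls a signal of 10.63 and 10.12 (p = 0.048, adjusted p = 0.36).

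The next comparison asked what the early, day 4 gland expressed 4 h after PGF2α. Of 38 measured chemokine and cytokine genes, 18 rose within 4 h (24 adjusted over the list alone), with a median of 0.80. FGF2 (281161), an angiogenic growth factor, rose from 4.18 ± 0.55 (SD, n = 5) to 8.64 ± 0.23 (SD, n = 5), or 22.1-fold. The FGF2 signal at 0 h was near background, so the size of the fold change is uncertain. PTGFR fell from 11.45 ± 0.09 (SD, n = 5) to 10.59 ± 0.18 (SD, n = 5).

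CCL4, a chemokine that attracts monocytes, rose by 4.64 ± 0.41 (SE), and IL33, a cytokine released by damaged cells, by 3.77 ± 0.23 (SE). IL1B, an inflammatory cytokine, rose by 3.69, AREG by 3.61, and CXCL8, which attracts neutrophils, by 3.42. The 0 h signals of IL1B and CXCL8, 4.53 and 5.11, were near background, so the size of their rises is uncertain. CCL8 and CCL2 (281043), which attract monocytes, rose by 3.10 and 2.23. In the cytokine receptor and NF-kB list 13 of 29 genes rose (17 adjusted over the list alone), including the NF-kB inhibitor NFKBIA by 2.24 and the adhesion molecule ICAM1 by 1.40. BIRC3 and BCL2A1, which block apoptosis, rose by 1.92 and 1.72. Of 24 immediate-early genes 11 rose (12 adjusted over the list alone), among them ATF3, a stress-induced transcription factor, by 1.47. NR4A1, a nuclear receptor of the immediate-early class, rose by 2.01 ± 0.49 (SE). The change of FOS, a subunit of AP-1, was 0.19 ± 0.41 (SE; adjusted p = 0.93).

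NDRG1, a hypoxia-induced gene, rose by 2.17 ± 0.23 (SE), and PFKFB3, which speeds glycolysis, by 1.47. TIMP3, an inhibitor of matrix proteases, rose by 1.39 and PLAUR by 1.18. EDN1, the vasoconstrictor endothelin, rose by 1.36 ± 0.30 (SE), and INHBA (281867), a subunit of activin and inhibin, by 1.69 ± 0.34 (SE). PTGS2, which makes prostaglandins, rose by 1.45 ± 0.35 (SE), a call lost without day 4, 4 h replicate 1 (adjusted p = 0.067, from 0.00033 to 0.067 over the alternatives). Its 0 h signal was near background at 4.11, and 1 of its 3 probe sets was called. PTHLH, a parathyroid hormone-related peptide, fell by 1.92 ± 0.24 (SE). POLR1E, a subunit of RNA polymerase I, fell by 1.23 ± 0.10 (SE). STAR changed by -0.15 (adjusted p = 0.88), CYP11A1 by -0.16 (adjusted p = 0.24) and HSD3B1 by -0.31 (adjusted p = 0.51). The test shared 1 spread over all groups, and the SD of HSD3B1 was 0.76 in the day 11, 24 h group. On day 4 HSD3B1 was 13.56 ± 0.08 (SD) at 0 h and 13.25 ± 0.10 (SD) at 4 h. The difference was larger than either SD, which argues for a small fall of HSD3B1 that the test with its shared spread did not call.

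In total 1018 probe sets changed, 645 higher and 373 lower, and 1544 had no overlap between groups (0.794% by chance). Without day 4, 4 h replicate 1 the count was 608, and with arrays weighted by their quality it was 1981. The chemokine, NF-kB, immediate-early, hypoxia and matrix protease lists were also called with an estimated correlation (adjusted p = 0.0026, 0.011, 0.033, 0.033 and 0.0034). The macrophage list was called with 1 member higher, and 5 adjusted over the list alone (adjusted p = 4.5e-05 by camera, adjusted p = 0.38 with an estimated correlation). The member called over all probe sets was CD14, a receptor for bacterial lipopolysaccharide, by 1.06, a call lost without day 4, 4 h replicate 1 (adjusted p = 0.076).

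The same 4 h comparison in the day 11 gland asked what the mature tissue, which regresses after PGF2α, expressed at that time. Of the 38 chemokine and cytokine genes 27 rose (27 adjusted over the list alone), with a median of 1.46. INHBA rose from 7.39 ± 0.58 (SD, n = 5) to 11.76 ± 0.11 (SD, n = 5), or 20.6-fold. VEGFA (281572), the growth factor that sustains luteal capillaries, fell from 11.26 ± 0.14 (SD, n = 5) to 10.48 ± 0.19 (SD, n = 5).

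GAL (280799), the neuropeptide galanin, rose by 5.95 ± 0.34 (SE), or 61.9-fold, and AREG by 5.24 ± 0.31 (SE). The 0 h signals of GAL and AREG, 3.97 and 3.76, were near background, so the size of their rises is uncertain. IL33 rose by 4.68, KRT18 by 4.67, the serpin SERPINA14 by 4.64 and CCL4 by 4.08. CCL8 rose by 3.89, IL1B by 3.68, CXCL8 by 3.28 and CCL2 by 2.80. The 0 h signals of IL33, SERPINA14, IL1B and CXCL8, 4.71, 4.11, 4.16 and 4.51, were near background with the same limit. NFKB1, a subunit of NF-kB, rose by 1.52 with 19 of 29 genes of its list (22 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation). ATF3 rose by 3.32 ± 0.30 (SE) and FOSB, another subunit of AP-1, by 3.24 ± 0.25 (SE). In all, 11 of 24 immediate-early genes rose (15 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation). MMP1, a collagenase, rose by 3.76 and PLAUR by 2.56, and 11 of 26 matrix protease genes rose and 1 fell (13 and 3 adjusted over the list alone). MMP1 was near background at 0 h, at 3.45, so the size of its rise is uncertain. SELP and SELE, which tether leukocytes to vessel walls, rose by 2.72 and 2.63. S100A12, a neutrophil protein, rose by 2.95 ± 0.46 (SE) with 5 of 12 neutrophil and eosinophil markers (5 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Of 20 macrophage markers 7 rose (8 adjusted over the list alone; adjusted p = 0.61 with an estimated correlation), and of 22 T and NK cell markers 1 rose (0 adjusted over the list alone; adjusted p = 0.50 with an estimated correlation).

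CFLAR, which blocks death receptor signaling, rose by 2.13 ± 0.18 (SE), and MT2A, a metal-binding protein, by 2.15 ± 0.27 (SE). PLIN2, which coats lipid droplets, rose by 1.52 ± 0.11 (SE). FGF2 rose by 2.34, EDN1 by 1.99 and THBS2, an inhibitor of angiogenesis, by 1.24. PTHLH fell by 1.92, APLNR, the apelin receptor of endothelial cells, by 1.66 and NR5A2, a nuclear receptor that drives steroidogenic genes, by 1.31. PTGFR fell by 0.52 ± 0.14 (SE), a call lost with array weights (adjusted p from 0.0052 to 0.053 over the alternatives). LHCGR fell by 0.90 ± 0.29 (SE), a call lost without day 11, 4 h replicate 1 or 2 or day 11, 0 h replicate 4 (adjusted p from 0.0084 to 0.11 over the alternatives). VEGFA fell by 0.78 ± 0.18 (SE); this was called with its representative probe set but not with the mean of its probe sets (adjusted p = 0.073, from 0.0011 to 0.073 over the alternatives). STAR changed by -0.25 (adjusted p = 0.47), CYP11A1 by -0.15 (adjusted p = 0.15) and HSD3B1 by -0.31 (adjusted p = 0.29). The test shared 1 spread over the groups, and STAR and HSD3B1 had SDs of 0.83 and 0.76 on day 11 at 24 h. STAR was 13.60 ± 0.10 (SD) at 0 h and 13.35 ± 0.08 (SD) at 4 h, without overlap between arrays. HSD3B1 was 13.71 ± 0.07 (SD) and 13.40 ± 0.07 (SD). Both differences were larger than the SDs of the groups compared. These values argue for small falls of both genes, which the test with its shared spread did not call. In the oxidative phosphorylation list 10 of 41 genes fell (14 adjusted over the list alone; adjusted p = 0.50 with an estimated correlation).

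Of 22 interferon-stimulated genes 9 rose (12 adjusted over the list alone), led by RSAD2 at 3.31 and ISG15 at 2.50, which limit virus replication (adjusted p = 0.50 with an estimated correlation). Without day 11, 4 h replicate 4, an alternative chosen after the data were seen, 6 of 22 were called and the list median went from 0.68 to 0.33. In total 4409 probe sets changed, 1927 higher and 2482 lower, and 2413 had no overlap between groups (0.794% by chance). A fit to the 10 arrays of this contrast called 2520. Day 11, 4 h replicate 1 stood apart in signs of RNA quality, with an EF1A 3′ minus 5′ difference of -1.40 (others -2.46 to -2.28) and a GAPDH difference of 0.09 (others 0.35 to 0.61), and had the lowest array weight (0.318). Without day 11, 4 h replicate 1 the count was 4002. The chemokine list and the matrix protease list were also called with an estimated correlation (adjusted p = 0.0043 for both).

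Whether the 4 h response differed between the days was tested by the interaction. Across probe sets, which are not independent replicates, the changes correlated at r = 0.64, and 967 of the 1018 probe sets called on day 4 had the same sign on day 11. Of 264 probe sets that differed, 174 had the higher response on day 11 and 90 the lower. KRT18 had a difference of 4.44 ± 0.40 (SE), day 11 minus day 4, and GAL of 4.11 ± 0.49 (SE). From 0 to 4 h KRT18 went from 12.37 to 12.60 on day 4 and from 7.27 to 11.94 on day 11, where it stayed lower. GAL went from 5.04 to 6.89 on day 4 and from 3.97 to 9.92 on day 11, with both 0 h signals near background. INHBA rose more on day 11 by 2.67 ± 0.48 (SE, adjusted p = 0.0029), and FGF2 rose less, with a difference of -2.13 ± 0.51 (SE, adjusted p = 0.031). FGF2 was at 8.64 on day 4 and 7.36 on day 11 at 4 h. At 0 h it was near background, at 4.18 and 5.02, so the size of its difference is uncertain.

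SERPINA14 had a difference of 3.17, and G0S2, which inhibits lipid breakdown, of 3.06. SELE had 2.46, MMP1 2.41, FOSB 2.03, ATF3 1.86, CSF1, a growth factor of macrophages, 1.56 and PLAUR 1.37. MMP1 was near background at 0 h, at 3.84 on day 4 and 3.45 on day 11, so the size of its difference is uncertain. Some of these genes started lower on day 11. SELE went from 6.32 to 6.49 on day 4 and from 4.13 to 6.76 on day 11. PLAUR went from 9.20 to 10.39 and from 7.69 to 10.25, and G0S2 from 10.12 to 9.41 and from 7.81 to 10.16. The 0 h means of FOSB and ATF3 were not lower on day 11. FOSB was at 5.31 ± 0.68 (SD) against 4.73 ± 0.27 (SD) and ATF3 at 6.77 ± 0.64 (SD) against 6.34 ± 0.31 (SD). On the negative side were SLCO2B1, an organic anion transporter, at -2.21, BCAT2, which breaks down branched-chain amino acids, at -1.80 and LPL at -1.64. CSF1, SLCO2B1 and BCAT2 have 2 probe sets each, of which 1 was called. Their other probe sets had differences of -0.02, -0.55 and -0.27. The differences of PTGFR (0.34, adjusted p = 0.55), STAR (-0.10, adjusted p = 0.95), VEGFA (-0.45, adjusted p = 0.54) and CCL2 (0.57, adjusted p = 0.71) did not pass. FGF2 lost its call without day 11, 0 h replicate 1, 3 or 4, day 4, 0 h replicate 3, 4 or 5, or day 4, 4 h replicate 2 (adjusted p from 0.0088 to 0.078 over the alternatives). ATF3 lost its call without day 4, 0 h replicate 3 or day 11, 4 h replicate 4 (adjusted p = 0.051 for both). In the chemokine list 2 of 38 genes differed (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.75 with an estimated correlation). Interferon-stimulated genes gave a limma count of 0 over all probe sets and of 8 adjusted over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.75 with an estimated correlation). Their median difference went from 0.77 to 0.43 without day 11, 4 h replicate 4. Without day 4, 4 h replicate 2 the count of differing probe sets was 157.

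At 24 h, the question in the day 4 gland was what remained of the response in tissue that does not regress. FGF2, CXCL8, CCL2 and PTGFR, changed at 4 h, did not differ from 0 h by the test. FGF2 stood at 4.59 ± 0.54 (SD, n = 5; adjusted p = 0.65) and PTGFR at 11.51 ± 0.29 (SD, n = 5; adjusted p = 0.91). Of 44 cell cycle genes 40 fell (42 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation), with a median of -1.26; the mean of the list was 8.82 to 9.08 in the arrays at 0 h and 6.42 to 8.89 in those at 24 h. CYP17A1 (281739), which makes androgens, rose from 5.67 ± 0.98 (SD, n = 5) to 8.97 ± 0.35 (SD, n = 5), or 9.86-fold.

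CDH8, a cell adhesion cadherin, rose by 2.09 ± 0.35 (SE) and GAL by 2.08 ± 0.34 (SE). GPC3, a surface proteoglycan, rose by 1.60, the water channel AQP11 by 1.59 and ALDH1A1, which makes retinoic acid, by 1.51. PTX3, a pentraxin of innate immunity, fell by 1.74 ± 0.37 (SE), and ZBTB16, a transcription factor, by 1.43 ± 0.25 (SE). These 7 genes and CYP17A1 were called under each alternative run for single genes. CCNB2, a mitotic cyclin, fell by 1.85, ASPM, a spindle protein, by 1.73, CDH1, the epithelial cadherin, by 1.19 and VCAM1, a leukocyte adhesion molecule, by 1.06, and CTSF rose by 1.06. These 5 genes lost their call in the fit to the 10 arrays of this contrast, with adjusted p = 0.098, 0.078, 0.053, 0.075 and 0.056, the highest over their alternatives. LHCGR rose by 1.15 ± 0.29 (SE), a call lost without day 4, 0 h replicate 1 or day 4, 24 h replicate 2 (adjusted p from 0.0029 to 0.068 over the alternatives). STAR changed by 0.22 (adjusted p = 0.70), HSD3B1 by 0.01 (adjusted p = 0.99), VEGFA by -0.24 (adjusted p = 0.57) and CCL2 by -0.88 (adjusted p = 0.11).

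In the lysosome and autophagy list 7 of 30 genes rose (15 higher and 1 lower adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). In the cholesterol list 4 of 27 rose (10 adjusted over the list alone; adjusted p = 0.65 with an estimated correlation). In the macrophage list and the T and NK cell list 0 of 20 and 0 of 22 genes were called, also when adjusted over the list alone, with medians of 0.56 and 0.25 (camera adjusted p = 0.0014 and 0.025, adjusted p = 0.76 with an estimated correlation for both). In the complement list 1 of 21 rose (1 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.00016, adjusted p = 0.65 with an estimated correlation). In total 1240 probe sets changed, 508 higher and 732 lower, and 1055 had no overlap (0.794% by chance). This count depended on single arrays. It was 357 without day 4, 24 h replicate 4, 497 without replicate 2 and 2071 without replicate 1 of that group, and 720 and 734 without day 4, 0 h replicates 3 and 4. A fit to the 10 arrays of this contrast called 147, of which 127 were among the 1240.

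**Figure D2:**
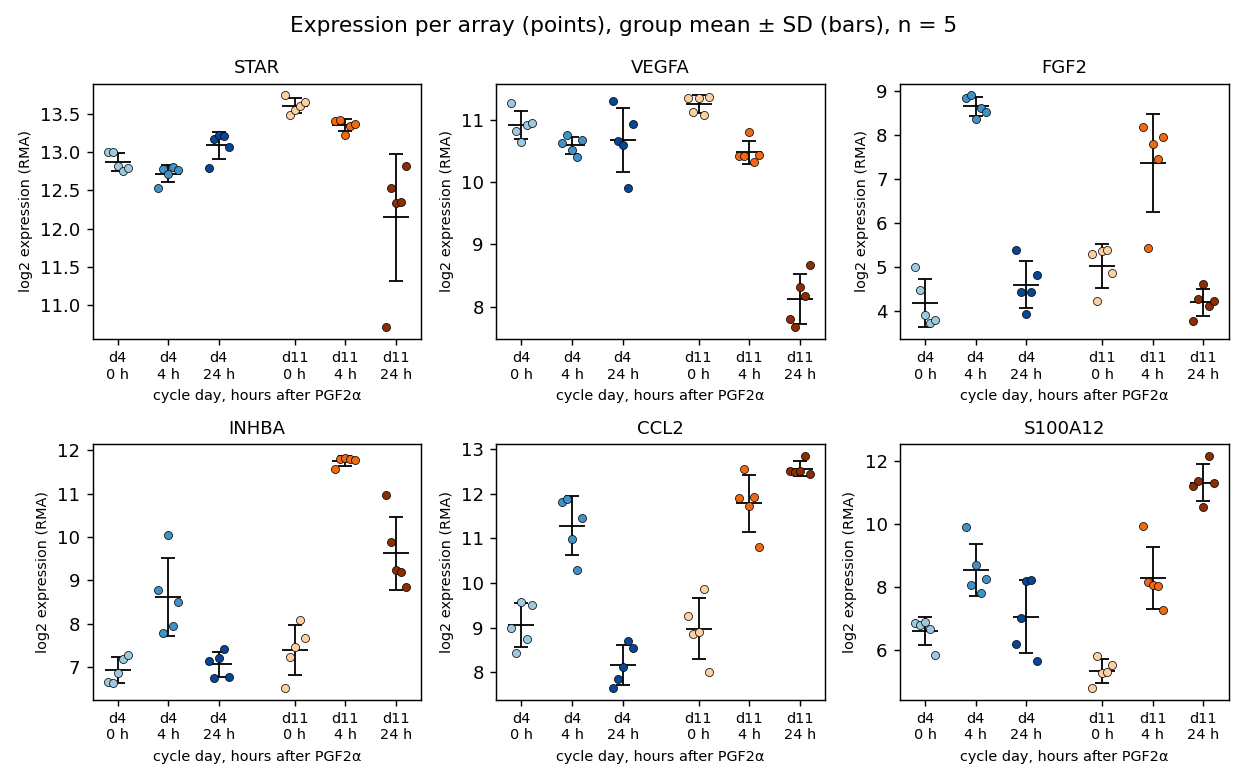
Log2 signal (vertical) of STAR, VEGFA, FGF2, INHBA, CCL2 and S100A12 by time after PGF2α in hours (horizontal), on day 4 and day 11; points are single arrays and the bars give mean ± SD of 5. VEGFA on day 11 goes from 11.26 at 0 h to 8.12 at 24 h, and FGF2 on day 4 peaks at 8.64 at 4 h.

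At 24 h in the day 11 gland, the comparison asked which genes accompany regression. HSD3B1, which makes progesterone, fell from 13.71 ± 0.07 (SD, n = 5) to 11.39 ± 0.76 (SD, n = 5), and STAR from 13.60 ± 0.10 (SD, n = 5) to 12.15 ± 0.83 (SD, n = 5). CCL2 rose from 8.98 ± 0.68 (SD, n = 5) to 12.56 ± 0.16 (SD, n = 5).

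CYP11A1 fell by 0.72 ± 0.07 (SE), LHCGR by 2.24 ± 0.29 (SE) and PTGFR by 0.96 ± 0.14 (SE). CYP19A1, the aromatase that makes estrogen, fell by 2.80 and NR5A2 by 2.33. Of the 20 steroidogenic enzymes and regulators 9 fell and 4 rose (9 and 4 adjusted over the list alone; adjusted p = 0.073 with an estimated correlation). Of the 27 cholesterol genes 19 fell and 6 rose (19 and 6 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). DHCR7, MVK and EBP, enzymes of cholesterol synthesis, fell by 2.09, 2.05 and 2.02. Of 41 oxidative phosphorylation genes 40 fell (40 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.073 with an estimated correlation). NDUFS3, a subunit of complex I, fell by 1.08 and CYC1, cytochrome c1, by 0.85. VEGFA fell by 3.13 ± 0.18 (SE), or 8.78-fold, and APLNR by 2.01. HPGD, which breaks down prostaglandins, fell by 2.01 and SLCO2A1, which takes them up, by 1.75. PTHLH fell by 3.67, and OXT did not pass the test (-0.07, adjusted p = 0.49).

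SERPINA14 rose by 6.82 ± 0.46 (SE), or 113-fold, GAL by 6.59 ± 0.34 (SE) and S100A12 by 5.97 ± 0.46 (SE). The 0 h signals of SERPINA14 and GAL, 4.11 and 3.97, were near background, so the size of their rises is uncertain. SLC2A5, a fructose transporter, rose by 5.07, IL1RN, which blocks interleukin 1, by 4.42, and FABP4, a fatty acid carrier of macrophages and fat cells, by 4.14. FBXO32, a ubiquitin ligase of tissue atrophy, rose by 4.01 and MMP1 by 3.95. MMP1 was near background at 0 h, at 3.45, so the size of its rise is uncertain. Of 20 macrophage markers 14 rose (16 adjusted over the list alone), with a median of 1.66 (adjusted p = 0.32 with an estimated correlation). FCGR2B, an antibody receptor, rose by 3.29, TYROBP, an adapter of myeloid receptors, by 2.61 and CD14 by 2.60. NKG7, a protein of cytotoxic lymphocytes, rose by 2.32 with 12 of 22 T and NK cell markers (12 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Of 38 chemokine and cytokine genes 18 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). SPP1, the cytokine osteopontin, rose by 3.85 and CXCL8 by 3.29. CXCL8 was near background at 0 h, at 4.51, with the same limit. CTSH and CTSK, lysosomal proteases, rose by 1.73 and 1.42 with 22 of 30 lysosome and autophagy genes (24 higher and 1 lower adjusted over the list alone; adjusted p = 0.084 with an estimated correlation).

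HMOX1, which degrades heme, rose by 2.90 ± 0.22 (SE). GADD45A, a growth arrest gene, rose by 2.16, the death receptor FAS by 1.33 and TGFB1, a growth factor that promotes fibrosis, by 1.98. THBS2 rose by 2.15 and EDN1 by 1.77. MMP19, a matrix protease, rose by 2.83, and 15 of the 26 genes of its list rose and 1 fell (15 and 1 adjusted over the list alone), the list here that was also called with an estimated correlation (adjusted p = 0.0062). In total 7121 probe sets changed, 3423 higher and 3698 lower, and 4980 had no overlap between groups (0.794% by chance). The EF1A control probe sets had a 3′ minus 5′ difference that was lower at 24 h by -0.29 than at 0 h, a sign of RNA state examined in addition to the planned ones (exact two-sided permutation p = 0.0079, the smallest that 5 against 5 can give, adjusted p = 0.24). The planned array median was 6.09 at 24 h and 6.07 at 0 h (exact two-sided permutation p = 0.04, adjusted p = 0.47).

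**Figure D3:**
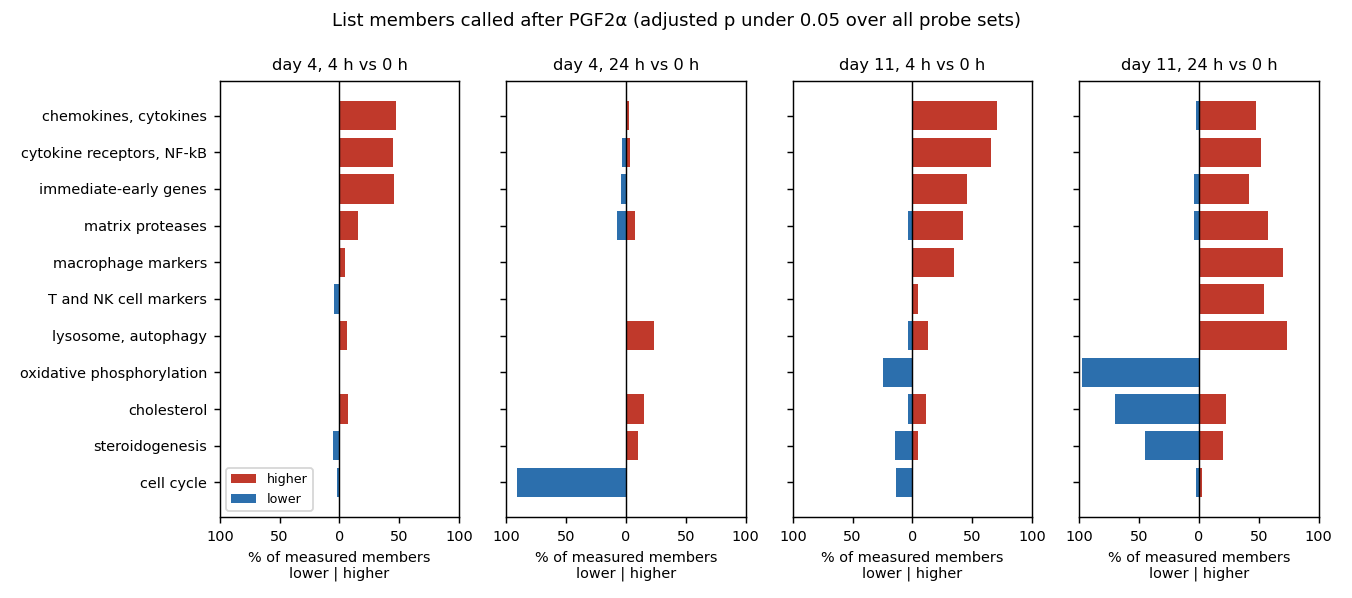
Percent of the measured genes of 11 lists that were called higher (right of 0) or lower (left of 0) in the 4 responses to PGF2α, from the limma fit over all probe sets. In the day 11, 24 h response 40 of 41 oxidative phosphorylation genes are lower, and in the day 4, 24 h response 40 of 44 cell cycle genes are lower.

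The 24 h responses of the 2 days were then compared by the interaction. Of the 20 steroidogenic genes 11 had a lower response on day 11 and 1 a higher one (11 and 1 adjusted over the list alone; adjusted p = 0.026 with an estimated correlation). LHCGR had a difference of -3.39 ± 0.41 (SE), HSD3B1 of -2.33 ± 0.27 (SE) and VEGFA of -2.89 ± 0.26 (SE). The changes on day 4 are part of these differences: LHCGR changed there by 1.15, HSD3B1 by 0.01 and VEGFA by -0.24. CCL2 had a difference of 4.46 ± 0.45 (SE), or 22.0-fold. Across probe sets, which are not independent replicates, the changes of the 2 days correlated at r = -0.01. No group received saline 24 h before collection, so these differences cannot separate PGF2α from a further day of the cycle.

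S100A12 had a difference of 5.52, SERPINA14 of 5.59, LOXL4 of 5.04, SLC2A5 of 4.89 and GAL of 4.51. STAR had -1.68 (adjusted p = 0.00012), CYP11A1 -0.88 (adjusted p = 1.7e-07) and PTGFR -1.02 (adjusted p = 0.00037). CYP19A1 had -2.98 and CYP17A1 -2.95. The difference of CYP17A1 came from a rise of 3.30 on day 4, and on day 11 CYP17A1 went from 6.36 to 6.71. MVK had -2.67 and DHCR7 -2.50, and 18 of 27 cholesterol genes were lower and 2 higher (18 and 3 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation). In the oxidative phosphorylation list 37 of 41 genes were lower (40 adjusted over the list alone; adjusted p = 0.090 with an estimated correlation). HSPE1, a mitochondrial chaperone, had -1.07 and ENDOG, a mitochondrial nuclease, -1.60. PTHLH had -3.60 and BCAT2 -3.94.

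MMP1 had a difference of 3.82 and PLAU, the urokinase protease, of 2.16, and 11 of 26 protease genes were higher and 2 lower (12 and 3 adjusted over the list alone; adjusted p = 0.042 with an estimated correlation). In the chemokine list 14 of 38 were higher (16 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation). In the macrophage list 9 of 20 were higher (10 adjusted over the list alone; adjusted p = 0.62 with an estimated correlation), led by FCGR2B at 3.30 and the scavenger receptor MSR1 at 2.24. SOCS3, a brake on cytokine signaling, had 2.51, CXCL8 3.40, FOS 2.20, EDN1 2.04 and INHBA 2.10. MMP1 and CXCL8 were near background at 0 h on both days, so the size of their differences is uncertain. MT2A had 3.65 and HMOX1 2.80. The 44 cell cycle genes had a median difference of 1.10, and 22 were higher (29 adjusted over the list alone; adjusted p = 0.62 with an estimated correlation), among them CDK1, the kinase of mitotic entry, at 2.78 ± 0.59 (SE). From 0 to 24 h the mean of this list went from 8.94 to 7.75 on day 4 and from 6.87 to 6.79 on day 11. In total 5342 probe sets differed, 2538 higher and 2804 lower. The 2 interactions tested jointly gave 5517.

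From 4 h to 24 h the course of the response was followed within each day. On day 11, 11 of 20 macrophage markers rose and 1 fell between these times (15 and 1 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation). Of 24 immediate-early genes 8 fell and 1 rose (9 and 3 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). FABP4 rose by 3.66 ± 0.32 (SE) and HMOX1 by 2.87 ± 0.22 (SE), and FOSB fell by 3.09 ± 0.25 (SE) and FGF2 by 3.17 ± 0.36 (SE). The changes of CCL2 (0.78, adjusted p = 0.080), CXCL8 (0.01, adjusted p = 0.99) and FOS (0.17, adjusted p = 0.83) did not pass the test. HSD3B1 fell by 2.00 and STAR by 1.20. CTSB, a lysosomal protease, rose by 1.21 with 21 of 30 genes of its list (22 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). RSAD2 and ISG15 fell by 2.70 and 2.36. FLT1, a receptor for vascular endothelial growth factor, fell by 2.30. In total 5570 probe sets changed, 2995 higher and 2575 lower, and 3687 had no overlap (0.794% by chance).

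On day 4, CCL4 fell between 4 and 24 h by 4.61 ± 0.41 (SE), FGF2 by 4.05 ± 0.36 (SE), CCL2 by 3.11 ± 0.32 (SE) and NDRG1 by 2.32 ± 0.23 (SE). PTHLH rose by 1.86 ± 0.24 (SE) and PTGFR by 0.92 ± 0.14 (SE). LHCGR rose by 1.55 and CYP11A1 by 0.32, and the change of NR4A1 did not pass the test (-1.02, adjusted p = 0.18). Of 38 chemokine genes 20 fell (23 adjusted over the list alone; adjusted p = 0.062 with an estimated correlation), and of 29 NF-kB genes 18 fell (19 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Of 44 cell cycle genes 33 fell (37 adjusted over the list alone; adjusted p = 0.44 with an estimated correlation), including CCNB1 by 1.93. In total 3580 probe sets changed, 1841 higher and 1739 lower, and 2880 had no overlap (0.794% by chance). Of 98 list calls made by camera over the 9 comparisons, the 10 given above with an estimated correlation under the threshold were also called that way.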

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

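The tests on leukocyte markers and the test without day 11, 4 h replicate 1 were chosen only after the result was seen.

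The responses of the days differed by the interaction tests, with 264 probe sets at 4 h, 5342 at 24 h and 5517 for both jointly. At 4 h the difference, day 11 minus day 4, was -2.13 for FGF2 (adjusted p = 0.031) and 2.67 for INHBA (adjusted p = 0.0029). At 24 h it was -1.68 for STAR, -0.88 for CYP11A1, -2.33 for HSD3B1, -3.39 for LHCGR, -1.02 for PTGFR and -2.89 for VEGFA. It was 2.04 for EDN1, 4.46 for CCL2, 3.40 for CXCL8, 2.20 for FOS and 2.10 for INHBA at 24 h.

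In 13 of 108 sets of 5 values (15 panel genes and 3 measures of array quality in 6 groups), 1 array stood far from the other 4, where chance gives about 1 in 20. STAR and HSD3B1 in day 11, 24 h replicate 1 were at 10.71 (others 12.33 to 12.82) and 10.06 (others 11.63 to 11.92). In day 11, 0 h replicate 4, LHCGR was at 8.92 (others 7.48 to 7.88) and PTGS2 at 4.61 (others 3.94 to 4.12). PTGFR was at 10.27 in day 4, 4 h replicate 1 (others 10.61 to 10.71) and at 10.44 in day 11, 4 h replicate 1 (others 10.96 to 11.14). In that same day 11, 4 h replicate 1, INHBA was at 11.56 (others 11.78 to 11.83) and the array median at 6.01 (others 6.07 to 6.08). VEGFA was at 10.80 in day 11, 4 h replicate 3 (others 10.32 to 10.43), and FGF2 at 5.42 in day 11, 4 h replicate 2 (others 7.46 to 8.17). CCL2 was at 12.84 in day 11, 24 h replicate 4 (others 12.45 to 12.52), CXCL8 at 5.92 in day 11, 0 h replicate 5 (others 3.99 to 4.54) and FOS at 8.62 in day 4, 0 h replicate 5 (others 9.86 to 10.19).

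Macrophage markers were higher 24 h after PGF2α on day 11, with a mean change of 1.56 over the list, and HBB, a red cell gene named for this test, changed by 0.08 (exact two-sided permutation p = 0.75). The macrophage mean rose by 1.54 more than the joint mean of endothelial, smooth muscle and fibroblast markers (exact two-sided permutation p = 0.0079, the smallest that 5 against 5 can give). That joint mean changed by 0.03. If luteal cells alone had been lost, the markers of all other cell types would have risen alike. The lists moved apart instead: fibroblast markers went from 9.70 to 9.99, endothelial from 7.79 to 7.65 and smooth muscle from 8.06 to 7.93. These values argue against a loss of luteal cells alone, but a smaller luteal share may still account for part of the rise. The median of the macrophage list was 1.66 as deposited and 1.65 after a further quantile normalization. RMA had already normalized between arrays, which this test could not undo, so it decides nothing about the authors' normalization. More blood in the tissue stays open, because HBB was near background at 5.25, at 36.7% of the ranked probe sets, and its low signal decides nothing. The values are consistent with more macrophages in the tissue or with higher expression per macrophage, which were not tested apart.

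The day 4 profile at 24 h lay toward the day 11 profile at 0 h: of the probe sets called in both comparisons, 406 were higher in both (82.1 if independent), 694 lower in both (129.5 if independent), and 18 and 0 opposite (89.9 and 118.2 if independent). Both comparisons share the day 4 controls, so the controls were split between them. The covariance across probe sets was then 0.0889, against -0.0016 to 0.0019 in simulations without changes. The simulations drew each probe set independently, whereas real genes vary together (estimated correlation 0.745 in the cell cycle list). Their range is therefore too narrow to exclude chance. Without any 1 of the 5 arrays at 24 h the covariance was at least 0.0688, which argues against a single array as the cause. The arrays themselves lay at 8.55, 49.8, 39.4, 68.2 and 23.0% of the way from day 4 to day 11 at 0 h. A further day of luteal growth without PGF2α may give the same profile (correlation 0.59 across probe sets with split controls), and cannot be told apart from an effect of PGF2α, because no group received saline 24 h before collection.

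Fewer probe sets differed between the days at 4 h than at 24 h, 264 against 5342. Leaving out day 11, 4 h replicate 1, whose array median stood apart and whose EF1A and GAPDH 3′ minus 5′ differences, -1.40 and 0.09, lay outside those of the other 4 (-2.46 to -2.28 and 0.35 to 0.61), gave 273 at 4 h, which argues against that array as the cause. The ratio of the median SD between arrays of the 4 h groups to that of the 24 h groups was 1.08. Both interactions used 1 spread per probe set shared by all groups. A wider spread at 4 h could thus not act through the standard error, and the ratio decides nothing. A biological difference in timing between the days stays open and was not tested.

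To see whether arrays grouped at random give counts as large, the fit was repeated on 100 groupings per comparison, the real one included. For comparisons of 2 groups, the arrays of both groups were split in other ways. For the interactions, group labels were shuffled over the residuals of an additive fit of day and time to all arrays. Those residuals still hold the real interactions, and the real counts came from the values themselves, so the interaction counts are not like for like. The real grouping gave the highest count in 9 of 10 comparisons, or 1 of 100, the smallest share possible here. For the comparisons of 2 groups among these, no other split drawn gave as many calls. The real and the highest other counts were 4409 and 1183 (day 11, 4 h), 7121 and 1982 (day 11, 24 h), 1018 and 255 (day 4, 4 h), 8128 and 3697 (days at 0 h), 264 and 2 (4 h interaction), 5342 and 184 (24 h interaction), 5570 and 974 (day 11, 24 h against 4 h), 3580 and 1105 (day 4, 24 h against 4 h) and 5517 and 1 (joint interaction). For day 4 at 24 h, 2 of 100 splits gave as many, with 1240 for the real one and 1272 for the one that exchanged day 4, 24 h replicate 1 and day 4, 0 h replicate 5. This share was not adjusted for the 10 comparisons, and a wrong grouping gave more calls, so chance is not excluded for this count. Day 4, 24 h replicate 1 lay nearest the controls, at 8.55% of the way to day 11.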

How the results depend on the processing

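The alternatives without day 11, 4 h replicate 4 were chosen only after the result was seen, and the other alternatives were planned. Quantile normalization, subtraction of array medians, leaving out dim probe sets, a variance trend and kept control probe sets left each count within 1.5 times the reported one. Signal over background limits the dim probe sets, and 5 arrays per group limit the interactions. Replicate numbers used as a block also stayed within it, with 4704 and 7427 for day 11 at 4 and 24 h, 1123 and 1390 for day 4 at 4 and 24 h, and 335 and 5607 for the 4 and 24 h interactions. The labels do not pair the heifers, and deviations of arrays with the same number correlated at -0.20 to 0.26; 19 of 30 arrays correlated best with their own number, a hint from the data and not from the design. On day 4 at 4 h the share of calls that were higher went from 63.4% to 59.0% with quantile normalization and to 53.2% with medians subtracted.

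An adjusted p under 0.01 gave 2599 for day 11 at 4 h, 464 for day 4 at 4 h, 306 for day 4 at 24 h, 94 and 3422 for the 4 and 24 h interactions, 1934 for day 4 at 24 h against 4 h and 3516 for the joint interaction. A change of at least 2-fold gave 659 and 1416 for day 11 at 4 and 24 h, 226 and 244 for day 4 at 4 and 24 h, 1360 for the days at 0 h, 129 and 1794 for the 4 and 24 h interactions, and 980 and 538 for 24 h against 4 h on day 11 and day 4. Both are lower by construction. The arrays of the contrast alone gave 2520 for day 11 at 4 h and 147 for day 4 at 24 h, with fewer arrays for the variance. Fewer arrays alone do not explain the drop, because day 4 at 4 h went from 1018 to 1164 in such a fit. On day 4 the mean of the cell cycle list had an SD of 0.12 at 0 h and 0.95 at 24 h. A spread shared by all groups does not reflect this. The median SD over probe sets was 0.165 and 0.17, and the cause of the drop was not tested. Array weights gave 1981 for day 4 at 4 h and 2356 for day 4 at 24 h; the cause was not tested.

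Leaving out 1 array in turn gave 608 (without day 4, 4 h replicate 1) to 1061 for day 4 at 4 h. For day 4 at 24 h it gave 357 (without day 4, 24 h replicate 4) to 2071 (without replicate 1 of that group), with 497 without its replicate 2, and 720 and 734 without day 4, 0 h replicates 3 and 4. The 4 h interaction went from 157 (without day 4, 4 h replicate 2) to 356. The other counts stayed within 1.5 times.

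Of 98 list calls, 10 held with an estimated correlation, 88 were lost and 0 reversed; fry gave 126 calls, with 17 lost and 45 gained. Of 974 called values of named genes, 178 lost their call without 1 array, 125 with the arrays of the contrast alone, 47 with the mean of all probe sets and 36 with array weights. With the mean of all probe sets, 4 reversed, to 0.18 for NDUFS3 (day 11, 4 h), -0.38 for HSPA1A (days at 0 h), -0.93 for CD40 (day 11, 24 h against 4 h) and -0.19 for ITPR1 (day 4, 24 h against 4 h), where probe sets of a gene differ in sign. The interferon list without day 11, 4 h replicate 4 had camera adjusted p = 0.0010 at 4 h on day 11, with 6 of 22 genes called, and 4.6e-05 in the interaction, with 0 of 22. With all arrays both calls were lost, at adjusted p = 0.50 and 0.75 with an estimated correlation, which was not run without that array.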

Other observations

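The tests of CYP17A1 and of the size of the 4 h response were chosen only after the result was seen.

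Of 18 genes of the insulin-like growth factor list, 7 rose and 2 fell on day 11 at 24 h (7 and 3 adjusted over the list alone; camera adjusted p = 0.047, adjusted p = 0.33 with an estimated correlation). IGFBP5 and IGFBP1, which bind insulin-like growth factors, rose by 2.65 ± 0.30 (SE) and 2.62 ± 0.35 (SE) at 24 h. STC1, a secreted glycoprotein that regulates calcium and phosphate, rose by 2.60 ± 0.23 (SE). In the 24 h interaction these genes had differences of 2.03, 2.78 and 2.79. MT1A, a metallothionein, rose by 3.12 and MGST1, a glutathione transferase, fell by 1.83. PF4, a platelet chemokine that myeloid cells also express, rose by 3.21. ENO2 and PFKFB3, of glycolysis, rose by 2.18 and 2.48, and DDIT4, a stress-induced brake on cell growth, fell by 1.98. PTGER4, a prostaglandin E2 receptor, rose by 1.73, and AGTR1, an angiotensin receptor, fell by 1.73.

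Of 31 hypoxia and glycolysis genes, 11 fell and 2 rose from 4 to 24 h on day 4 (13 and 2 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). ANGPT2, which loosens vessel walls, rose by 1.02 ± 0.20 (SE) at 4 h and fell by 1.18 ± 0.20 (SE) from 4 to 24 h. EPAS1, a hypoxia-inducible transcription factor, rose by 0.71 and then fell by 1.01. PDE8A, which breaks down cAMP, rose by 0.64 and fell by 0.87, and TIMP3 fell again by 1.31. IGFBP1 rose by 1.48 at 4 h and fell by 1.64, the rise lost without day 4, 4 h replicate 1 (adjusted p from 0.0020 to 0.057 over the alternatives).

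Genes that changed 24 h after PGF2α on day 11 tended to be those that differed between the days at 0 h, in the opposite direction. Of the probe sets called in both, 1413 were higher on day 11 at 0 h and fell with PGF2α (597.3 if independent), and 893 were lower on day 11 and rose (605.6 if independent). In the same direction, 558 were higher in both (552.9 if independent) and 613 lower in both (654.3 if independent). With the shared day 11 controls split, the covariance was -0.0391, against -0.0019 to 0.0016 in simulations without changes. Part of the day 11 profile may have moved back toward that of day 4, as a hypothesis. On the way from day 4 to day 11 at 0 h, the day 11 arrays lay at 82.9 to 109% at 0 h. They lay at 81.8 to 87.6% at 4 h and at 74.1 to 86.3% at 24 h. The shift was thus small and already present at 4 h. The mean of the cell cycle list did not move back, at 6.87 and 6.79 on day 11 against 8.94 on day 4 at 0 h. The correlation across probe sets was weak, -0.14. The simulations drew each probe set independently, so their range is too narrow to exclude chance.

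CYP17A1 rose by 3.30 on day 4 at 24 h. If the granulosa and theca markers had risen as a group, the other 15 markers would have moved with it, but their median change was 0.03 (SD 0.43, from -1 to 1.15). What raised CYP17A1 stays open.

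Whether the 4 h response of the same genes was larger on day 11 was asked for 67 chemokine and NF-kB genes. Their mean change was 1.16 on day 11 and 0.98 on day 4, a difference of 0.17 with a standard error of 0.20 (permutation p = 0.48, 100000 permutations). A larger response may or may not exist, and 5 arrays per group did not decide it.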
